A study of Bacillus subtilis subsp. subtilis str. 168 with 3 samples.

How the data were processed

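RNA of a wild type laboratory strain of Bacillus subtilis was compared before and 10 min after exposure to 50 µM sodium hypochlorite (NaOCl, the active compound of bleach). Per the labels' protocols, the cells grew in minimal medium at 37 °C and were treated at an optical density of 0.4. RNA came from 3 independent cultures. Each culture gave 1 Agilent array with 2 dye channels, untreated RNA in Cy3 and treated RNA in Cy5. No array had the dyes swapped, so an effect of the dye on a gene stays in its mean ratio.

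The gene table deposited by the authors holds 1 linear ratio per gene and array, treated over untreated by its column names, for 4105 genes. Per the file headers, each ratio is an error-weighted average of the probe ratios of a gene of the SubtiList annotation, made with Rosetta Resolver 7.2.1. Agilent Feature Extraction 10.5 is named in the submitters' processing notes. The background correction and the dye normalization are not given in the sources used here. The median ratio was 1.028, 0.9967 and 0.9941 on the arrays of replicates 1, 2 and 3, so each change is relative to the typical gene and a shift shared by all genes would not be seen. A second deposited table holds values for 41882 array features on what the quantiles show to be a log10 scale, with a median of 0 on each array. Its direction and centring are unstated, and its features carry numbers without gene names. The plan fixed before the data were examined took the median over the probes of each gene, which needs those names, so the authors' gene ratios were used instead and the feature table served only for checks. Signal intensities were not used here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision.

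Ratios were put on the log2 scale with no further normalization. Each gene's mean log2 ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all 4105 genes and a threshold of 0.05. Gene names and locus tags are those of the deposited table, with current symbols from the RefSeq table of assembly ASM904v1 through the older locus tags, which matched 4037 genes and left 68 unmatched. The genome build of the array is not given in the sources used here, so no coordinates are printed. The ± values are SDs of the log2 ratio over 3 arrays. On simulated arrays with the spread of these data and 4105 genes, 3905 genes were unchanged, with 4 false calls among them. The test recovered 47.0% of genes changed by 0.5 on the log2 scale, 77.6% of those changed by 1 and 97.0% at 2. In the data 73.1% of genes were called. The cutoff that the adjustment sets depends on the share of changed genes, so these percentages do not give the recovery in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

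Before the data were examined, 27 gene lists with 447 genes were fixed from textbook knowledge and with the study known in outline, so the lists of stress genes are not independent of it. All 447 were found in the gene table. The lists hold chosen members, and counts given for a regulon refer to its list. Each list was tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 27 lists), which compares a list with the other genes. Camera was repeated with an estimated correlation, which refers to 2 residual degrees of freedom. On simulated arrays of 4105 genes, 1 of 10 lists of 20 genes was moved by 1 on the log2 scale. It was called with the preset and missed with the estimated correlation, which had little power there. The simulated genes were independent of each other. For the lists called with the preset, the estimated correlation ran from 0.019 (quinone and electrophile regulators) to 0.981 (OhrR), and was 0.705 for SigB. The simulation therefore does not show that the preset suits lists whose genes move together. Limma's fry, which tests whether the genes of a list move on balance one way, was the alternative. One alias in the fixed lists was wrong for hypR, pointing to ybfI. After the values had been seen, current symbols were given precedence over aliases, which moved this member to the gene now named hypR.

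The genes named in the text follow a rule fixed beforehand: among genes past the threshold with 1 sign on all arrays, the 14 with the highest and the 10 with the lowest mean, and for each list up to 4 members past the threshold with the largest change. This gave 114 genes, and any other gene named was chosen after its values were seen. Another 6 lists were written after results had been seen. In the added lists and operons, 4 members first pointed to another gene of the same symbol, which was noticed and put right after the results had been seen. With the wrong genes the PhoP list had an adjusted p of 0.0430 in camera (limma, Benjamini-Hochberg) in place of 0.0598, and the test of operon order kept 8 operons with a mean of -0.155 (permutation p = 0.349) in place of 9 with -0.067 (0.66). Alternatives were centring each array on its median, scaling arrays to 1 spread, quantile normalization, the robust form of eBayes, limma's treat against a fold of 1.2 and leaving out each array. After seeing the data, a requirement of 1 sign on all 3 arrays and a test of the array features were added.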

Results

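The response of growing Bacillus subtilis to hypochlorite was measured on 3 arrays, each setting the RNA of a culture 10 min after 50 µM NaOCl against untreated RNA. Ratios of 4105 genes were available on every array. The question was which genes change in transcript level under hypochlorite, an oxidant that attacks protein thiols. Pearson's r of the log2 ratios, taken across genes, which are not independent replicates, was 0.94 between replicates 1 and 2 and 0.924 for each pair with replicate 3. The SD over the arrays had a median of 0.176 on the log2 scale, and 62 genes had an SD over 1.

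The gene with the highest ratio was ohrA (yklA), which encodes an enzyme that reduces organic hydroperoxides. It rose 219-fold (log2 ratio 7.78 ± 0.22, SD, n = 3), with ratios of 247, 185 and 230 on the 3 arrays. The vegetative catalase gene katA rose 72.5-fold (6.18 ± 0.32), and yhdJ rose 67.2-fold (6.07 ± 0.04). At the other end, pyrB and pyrC of pyrimidine synthesis fell 99.1-fold (-6.63 ± 0.60) and 93.4-fold (-6.55 ± 0.44), and pbuG, a purine permease gene, fell 48.4-fold (-5.60 ± 0.10). The other genes of the highest 14 were cadA, yrdP, trxA, nfrA, ybcL, ywnF, yugS, hypR, yfhJ, hypO and ybyB, with log2 ratios from 5.82 down to 5.11. The remaining genes of the lowest 10 were argC, artP, pyrAA, argG, pyrP, argJ and argH, between -5.46 and -4.71. In limma with Benjamini-Hochberg adjustment, ohrA had an adjusted p of 5.15e-05 and pyrB one of 5.55e-05.

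**Figure D1:**
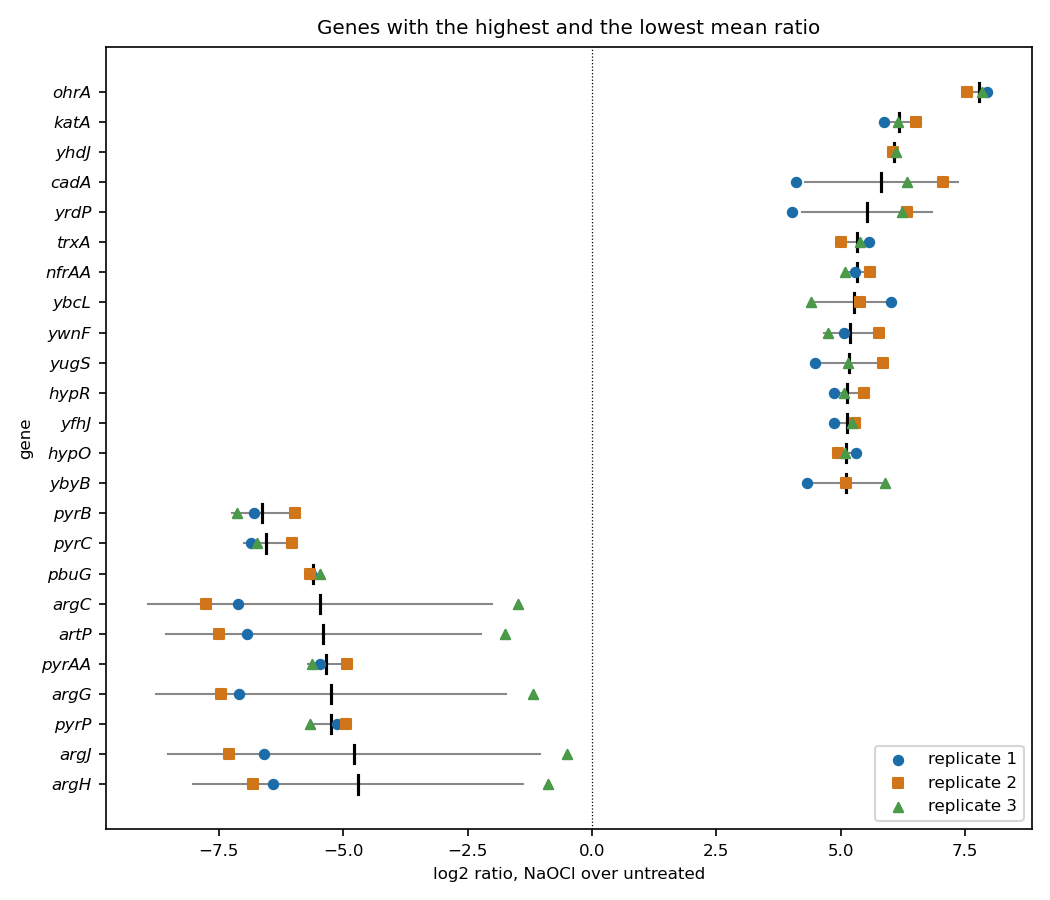
Log2 ratio of NaOCl-treated over untreated RNA for the 14 highest and 10 lowest genes named by rule, with 1 symbol per array, a black bar at the mean and a grey line for the SD (n = 3). The ohrA points lie together near 7.78, while argC, artP, argG, argJ and argH lie less far below 0 on the array of replicate 3, at ratios of 0.358, 0.297, 0.437, 0.710 and 0.542, than on the others.

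Past the threshold of the limma test, 1500 genes were higher and 1501 lower, 73.1% of the genome's measured genes, and 1104 were not called. Of these, 768 were at least 2-fold higher and 799 at least 2-fold lower, and 76 and 54 genes reached 10-fold. The sign was the same on all 3 arrays for 3440 genes (83.8%, where independent random signs would give 25%). A dye effect shared by the arrays would also give equal signs, so 25% is not the share expected without a response. Of the called genes 2 had mixed signs, ybxH and argD, named after their values were seen. As the arrays held no dye swap, a part of the small changes can carry a dye effect.

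Most listed genes controlled by thiol-sensing and peroxide-sensing regulators rose. Of the 17 listed genes of the Spx regulon, which answers disulfide stress, 16 were higher, the same number when adjusted over the list alone. The largest rises were those of thioredoxin trxA (5.32 ± 0.28), the oxidoreductase gene nfrA (5.32 ± 0.25), methionine sulfoxide reductase msrA (4.50 ± 0.11) and yugJ (4.19 ± 0.07), and the exception yjbC had a log2 ratio of -0.43. Both OhrR genes rose, ohrA as above and the regulator ohrR 2.67-fold (1.42 ± 0.02), also when adjusted over the list alone. In the PerR regulon of the peroxide response 11 of 13 genes were higher, 11 adjusted over the list alone, led by katA, zosA (4.81 ± 0.58), the DNA-protecting mrgA (3.67 ± 0.41) and alkyl hydroperoxide reductase ahpC (3.65 ± 0.23). Camera with Benjamini-Hochberg adjustment gave 2.85e-06 for Spx (median log2 ratio 3.37), 0.0496 for OhrR (4.60) and 5.94e-04 for PerR (1.72). Each of these had an adjusted p = 0.562 with an estimated correlation (limma camera). The OhrR call was also lost with arrays scaled to 1 spread (0.0677 in limma) and without replicate 1 (0.0506) or replicate 3 (0.051).

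Among the 10 genes for synthesis and use of bacillithiol, the low molecular weight thiol of this organism, 6 were higher, 2 lower and 2 not called, with the same counts adjusted over the list alone. The bacilliredoxin-like ytxJ (2.71 ± 0.46), bshB2 (2.57 ± 0.01), bshC (1.59 ± 0.11) and brxB (1.56 ± 0.17) changed most, and the lower genes were bstA (-0.97) and bshA (-0.25). The list as a whole did not pass limma's camera (median 0.776, Benjamini-Hochberg adjusted p = 0.137), while fry called it.

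Clp protease genes rose, while the HrcA list held genes of both directions. All 6 genes of the CtsR regulon, which holds the Clp protease genes, were higher, and all 6 adjusted over the list alone: clpE (4.77 ± 0.49), clpC (2.93 ± 0.32), mcsB (2.54 ± 0.57) and mcsA (2.51 ± 0.69) led. Camera (limma, Benjamini-Hochberg) gave an adjusted p of 0.00541 for this list, and adjusted p = 0.562 with an estimated correlation. In the HrcA regulon 5 of 9 genes were higher and 4 lower, equally so adjusted over the list alone. The chaperonin genes groES (2.53 ± 0.31) and groEL (1.51) rose, as did the repressor gene hrcA (2.08 ± 0.63), grpE (1.05) and dnaK (1.01). The methyltransferase genes prmA (-2.79 ± 0.23) and rsmE (-2.35 ± 0.18) fell, as did mtaB (-1.86) and dnaJ (-1.77). The HrcA list had a median of 1.01 and a mean of -0.066, so median and mean differed in sign, as did camera (up) and fry (down), neither past the threshold (camera, limma with Benjamini-Hochberg, adjusted p = 0.977).

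**Figure D2:**
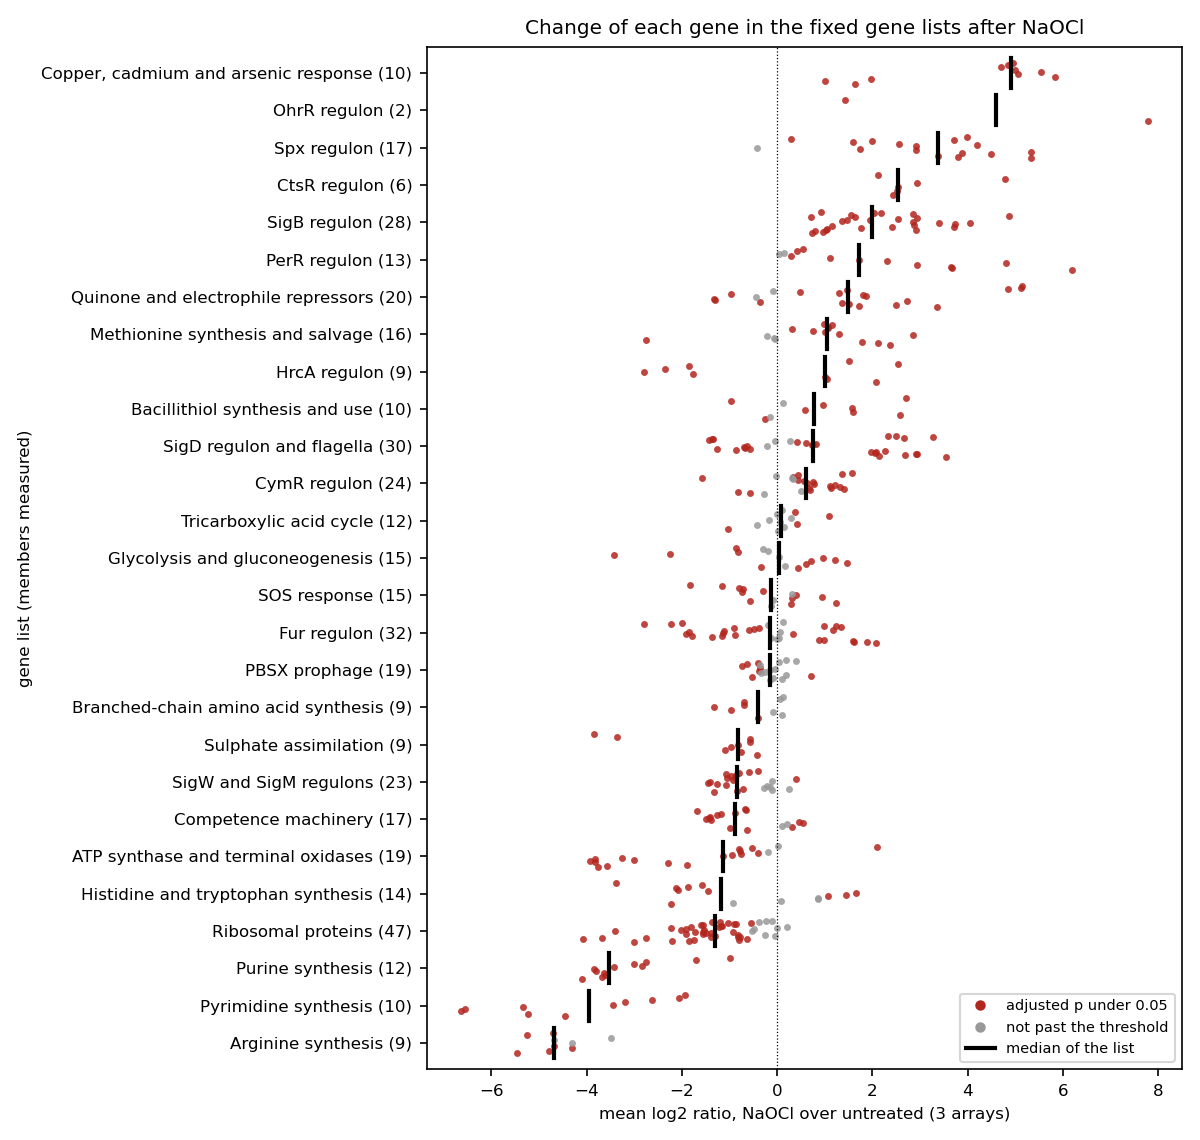
Mean log2 ratio of NaOCl over untreated (n = 3) for every gene of the 27 fixed lists, 1 point per gene, red where the limma adjusted p was under 0.05, with a black bar at the list's median. Medians run from 4.90 for the metal response to -4.69 for arginine synthesis.

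Metal efflux and general stress genes rose as well, and so did most genes under the electrophile regulators. All 10 genes of the copper, cadmium and arsenic response were higher, all 10 adjusted over the list alone, with cadA (5.82 ± 1.54), czcO (in the list of highest genes as yrdP, 5.53 ± 1.31), czcD (5.05 ± 1.6) and arsR (4.99 ± 0.34) in front. The first 3 varied between arrays: cadA had ratios of 17.1, 132 and 80.2, and without replicate 1 the means of cadA, yrdP and czcD were 6.69, 6.29 and 5.97. Without replicate 2, cadA was at 5.21. All 28 listed genes of the SigB general stress regulon were higher, all 28 adjusted over the list alone. Among them were nhaX (4.87 ± 0.25), the ribosome hibernation factor hpf (4.05 ± 0.15), yflT (3.73 ± 0.57) and gspA (3.72 ± 0.36). Of 20 genes under the quinone and electrophile regulators 14 were higher, 4 lower and 2 not called. Adjusted over the list alone, the counts were 14, 5 and 1. The hypochlorite-sensing regulator hypR (5.13 ± 0.30) and its target hypO (5.11 ± 0.18), yraA (4.85 ± 0.07) and the azoreductase azoR1 (3.35 ± 0.28) rose most, and mhqO (-1.32), mhqN (-1.30), mhqR (-0.97) and catR (-0.37) fell. Camera in limma with Benjamini-Hochberg adjustment gave 1.77e-04 for metals (median 4.90), 1.30e-07 for SigB (2.00) and 0.0076 for the electrophile regulators (1.48). All had an adjusted p = 0.562 with an estimated correlation (limma camera).

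Sulphur genes moved in different directions. In the CymR regulon of cysteine metabolism 16 of 24 genes were higher, 3 lower and 5 not called, against 18, 4 and 2 adjusted over the list alone. Cysteine synthase cysK rose (1.57 ± 0.27), as did snaA (1.40 ± 0.62) and ssuD (1.37 ± 0.30), while the cystine transporter gene tcyP fell (-1.57 ± 0.10), with mtnN (-0.83) and mccB (-0.58). All 9 genes of sulphate assimilation were lower, all 9 adjusted over the list alone, chiefly the sulphite reductase genes cysJ (-3.85 ± 0.22) and cysI (-3.35 ± 0.25), then sat (-1.09 ± 0.25) and cysC (-0.96 ± 0.28). Of 16 methionine genes of the S-box regulon 12 were higher, 1 lower and 3 not called, with equal counts adjusted over the list alone. The rises were largest for yitJ (2.84 ± 0.43), methionine synthase metE (2.36 ± 0.45) and metI (2.11 ± 0.21), and metK, which encodes S-adenosylmethionine synthetase, fell (-2.75 ± 0.15). Limma's camera with Benjamini-Hochberg adjustment gave 0.0171 for CymR (median 0.599), 0.00365 for sulphate assimilation (-0.833) and 0.0111 for methionine (1.04). For CymR and sulphate the adjusted p = 0.562 with an estimated correlation (limma), and for methionine it was 0.692.

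Iron, DNA damage and envelope stress lists differed. In the Fur regulon of iron uptake 11 of 32 genes were higher, 15 lower and 6 not called, the same adjusted over the list alone: dhbA of siderophore synthesis rose (2.08 ± 0.09) and the uptake genes yfiY (-2.80 ± 0.15), yfiZ (-2.23 ± 0.21) and yfhA (-2.0 ± 0.17) fell. Of 15 LexA-controlled genes of the SOS response 5 were higher, 7 lower and 3 not called, likewise adjusted over the list alone. The polymerase gene dinB (1.23 ± 0.18) and ynzC (0.93 ± 0.16) rose, and DNA ligase ligA (-1.82 ± 0.27) and helicase pcrA (-1.17 ± 0.30) fell. In limma's camera with Benjamini-Hochberg adjustment neither list passed (0.537 for Fur, median -0.156, and 0.561 for SOS, median -0.137). In the SigW and SigM regulons of cell envelope stress 16 of 23 genes were lower, 1 higher and 6 not called, as they were adjusted over the list alone, the higher gene being yuaI (0.39), with yknY (-1.45 ± 0.08), yknZ (-1.41 ± 0.05), sigW itself (-1.33 ± 0.18) and yknX (-1.27 ± 0.07) the lowest. Camera gave an adjusted p of 0.00114 (limma, Benjamini-Hochberg; median -0.853), and adjusted p = 0.562 with an estimated correlation.

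Among genes of cell subpopulations and phage, motility genes went both ways. Of 30 genes of motility and the SigD regulon 18 were higher, 9 lower and 3 not called, equally adjusted over the list alone. Flagellin hag (3.54 ± 0.24), the chemoreceptor gene mcpB (3.26 ± 0.17), flgM (2.94 ± 0.21) and fliT (2.91 ± 0.21) rose. The lower genes included flhA (-1.43), flhB (-1.36), flhF (-1.34), cheB (-1.27) and the sigma factor gene sigD itself (-0.64). By locus tag, the 9 lower genes lay in a run from flhB to sigD. Members outside the stretch from flgB to sigD were all higher. The list did not pass limma's camera (median 0.742, Benjamini-Hochberg adjusted p = 0.063), though without replicate 1 it did, at 0.0408 (median 0.86), with an adjusted p = 0.7085 there with an estimated correlation. Competence genes for DNA uptake were lower in 12 of 17 cases, 3 higher (comFB 0.54, comFC 0.46 and comEB 0.31) and 2 not called, the same when adjusted over the list alone: comC (-1.69 ± 0.09), comGB (-1.49 ± 0.05), comGC (-1.44 ± 0.05) and comGD (-1.42 ± 0.06) fell. Camera gave 0.0167 for competence (limma, Benjamini-Hochberg; median -0.894) and adjusted p = 0.562 with an estimated correlation. Of 19 genes of the defective prophage PBSX 6 were lower, 1 higher and 12 not called (5, 1 and 13 adjusted over the list alone), among them xkdO (-0.73 ± 0.21), xkdA (0.71 ± 0.04), xkdQ (-0.64 ± 0.23) and xtmB (-0.53 ± 0.18). That list did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.338, median -0.157).

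Most ribosomal protein and ATP synthase genes fell, and glycolysis and the tricarboxylic acid cycle held genes of both directions. Of 47 ribosomal protein genes 38 were lower, 0 higher and 9 not called, also adjusted over the list alone, and rplJ (-4.08 ± 0.31), rplL (-3.68 ± 0.38), rpsD (-3.41 ± 0.26) and rplA (-3.0 ± 0.07) were the lowest. The ATP synthase and terminal oxidase list had 16 of 19 genes lower, 1 higher and 2 not called, likewise adjusted over the list alone. The synthase genes atpF (-3.93 ± 0.11), atpE (-3.83 ± 0.14), atpH (-3.82 ± 0.06) and atpA (-3.76 ± 0.16) fell most, and the oxidase gene cydA rose (2.10). Camera in limma with Benjamini-Hochberg adjustment gave 1.94e-07 for ribosomal proteins (median -1.30) and 6.09e-05 for the ATP synthase list (-1.13). The adjusted p was 0.623 with an estimated correlation for the former and 0.562 for the latter (limma camera). Glycolysis held 6 genes higher, 5 lower and 4 not called of 15, the same when adjusted over the list alone, with the pyruvate dehydrogenase genes pdhA (-3.42 ± 0.33) and pdhB (-2.26 ± 0.38) lower and gapA (1.46 ± 0.16) and pgm (1.22 ± 0.19) higher. Its median was 0.034 and its mean -0.174. In the tricarboxylic acid cycle 3 of 12 genes were higher, 1 lower and 8 not called (2, 1 and 9 adjusted over the list alone): sdhB (1.08 ± 0.25), odhB (0.41 ± 0.27) and fumarase citG (0.38 ± 0.07) rose and aconitase citB (-1.04 ± 0.08) fell. The calls of odhB and citG were lost without replicate 2, and that of odhB also without replicate 3. Neither glycolysis (0.863) nor the cycle (0.691, median 0.079) passed camera in limma with Benjamini-Hochberg adjustment.

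Genes of pyrimidine and purine synthesis fell on each of the 3 arrays. All 10 pyrimidine genes were lower, all 10 adjusted over the list alone, with pyrAA (-5.34 ± 0.36) and pyrP (-5.24 ± 0.38) next after pyrB and pyrC. All 12 purine genes were lower, all 12 adjusted over the list alone, among them purE (-4.09 ± 0.58), purQ (-3.86 ± 0.39), purS (-3.80 ± 0.35) and purK (-3.68 ± 0.62). Camera in limma with Benjamini-Hochberg adjustment gave 3.67e-05 for pyrimidine (median -3.95) and 6.01e-05 for purine synthesis (-3.52). Both had an adjusted p = 0.562 with an estimated correlation (limma camera).

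**Figure D3:**
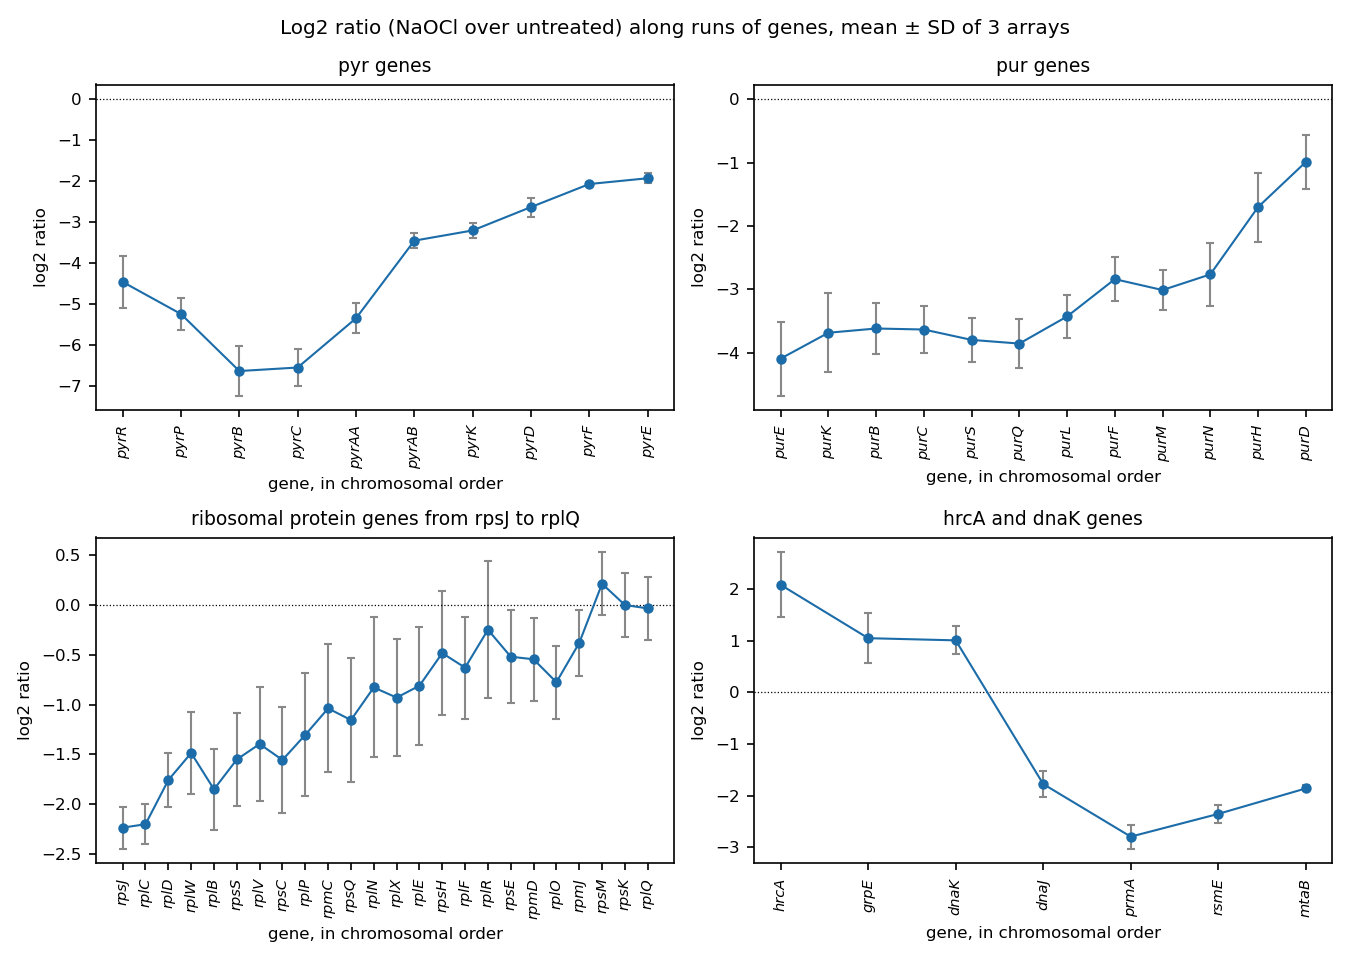
Log2 ratio of NaOCl over untreated along 4 runs of genes in chromosomal order, points for the mean and bars for the SD of 3 arrays. The decrease is smaller at the end of the pyr, pur and ribosomal protein genes, while in the hrcA and dnaK genes the values turn from above to below 0.

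Amino acid synthesis genes were mixed. In the arginine list 6 of 9 genes were lower and 3 not called, also adjusted over the list alone, but 0 were called without replicate 1 or without replicate 2 and all 9 were lower without replicate 3. The called argC (-5.46 ± 3.46), argG (-5.25 ± 3.52), argJ (-4.79 ± 3.74) and argH (-4.71 ± 3.32) had a large spread. Their decrease was smaller on the array of replicate 3, where argC, argG, argJ and argH had ratios of 0.358, 0.437, 0.710 and 0.542: the list's median log2 ratio was -6.58 and -7.30 on the arrays of replicates 1 and 2 and -0.30 on that of replicate 3. The arginine list missed the threshold in limma's camera (median -4.69, Benjamini-Hochberg adjusted p = 0.063) and passed it without replicate 3 (-6.94, 8.29e-06), with an adjusted p = 0.708 there with an estimated correlation. Without replicate 3, the means of argC, artP, argG, argJ and argH were -7.44, -7.22, -7.28, -6.94 and -6.62. The calls of argC, argG, argJ and argH were lost without replicate 1 (means -4.62, -4.33, -3.90 and -3.85) and without replicate 2 (-4.30, -4.15, -3.54 and -3.65), and artP, at -4.63 without replicate 1, lost its own without replicate 2 (-4.35). Of 14 histidine and tryptophan genes 7 were lower, 3 higher and 4 not called, the same adjusted over the list alone: trpA (-3.39 ± 0.02), hisZ (-2.24 ± 1.11, or -2.88 without replicate 3), trpC (-2.11 ± 0.20) and trpD (-2.08 ± 0.15) fell, and hisI (1.65), hisF (1.44) and hisA (1.06) rose. Of 9 branched-chain amino acid genes 5 were lower and 4 not called (4 and 5 adjusted over the list alone), leuB (-1.33 ± 0.19), leuA (-0.97 ± 0.15), leuC (-0.69 ± 0.25) and leuD (-0.69 ± 0.17) the lowest. Neither list passed camera (limma, Benjamini-Hochberg adjusted p = 0.187 for both, medians -1.19 and -0.405).

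**Figure D4:**
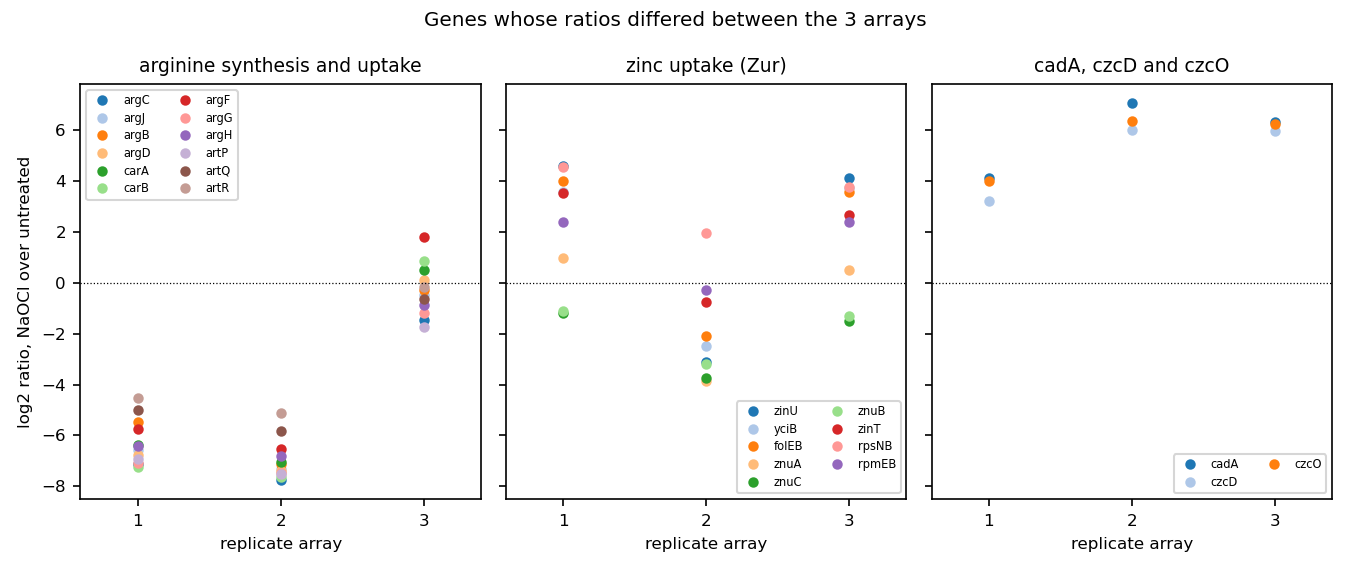
Log2 ratio of NaOCl over untreated on each array for the genes of arginine synthesis and uptake, the zinc uptake regulon and cadA, czcD and czcO, 1 point per gene. The arginine genes have a median of -0.40 on the array of replicate 3, with members on both sides of 0, 8 of the 9 zinc genes lie below 0 on that of replicate 2, and cadA, czcD and czcO are lowest on that of replicate 1.

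Of the 27 lists, 9 were called higher, 7 lower and 11 not called by limma's camera with its preset correlation. With an estimated correlation camera called 0, and 0 also at an unadjusted p under 0.05, while fry called 20.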

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

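The counts of genes higher and lower, and of those at least 2-fold changed, stayed within 1.5 times of their values under every gene-level alternative run. Called genes numbered 3016 with centred arrays, 3007 with scaled arrays, 3016 after quantile normalization, 3004 with robust eBayes and 2446 with treat against 1.2-fold. Without replicates 1, 2 and 3 they numbered 2876, 2603 and 2614. Of the 3001 called genes 0 changed sign, which was mostly fixed in advance. Of them, 2999 had 1 sign on all arrays, so leaving out or scaling an array could not turn their means. Robust eBayes, treat and the requirement of 1 sign left the means as they were. Among all alternatives run, the requirement of 1 sign on all arrays (2999 genes) and the test of array features were chosen after seeing the data. By features, 11761 of 41882 were called with a mean above 0 and 11732 with a mean below 0, or 56.1% called. When those at 0 on any array were left out, the counts were 12574 and 12646 of 37614, or 67% called. The direction of that table is unstated, and the counts swap if it is reversed. The lowest correlation between arrays was 0.924 over all genes; the 0.951 over called genes alone is raised by the calling, which favours genes alike on all arrays.

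With an estimated correlation in camera, 0 lists were called and the 16 lists called with the preset lost their call. The medians were as before: OhrR 4.60, Spx 3.37, CtsR 2.53, PerR 1.72, SigB 2.00, quinone and electrophile regulators 1.48, metals 4.90 and CymR 0.599. The others were sulphate -0.833, methionine 1.04, SigW and SigM -0.853, competence -0.894, ribosomal proteins -1.30, ATP synthase -1.13, purine -3.52 and pyrimidine -3.95. The lowest adjusted p with an estimated correlation was 0.562 (limma), and this test refers to 2 residual degrees of freedom. The list of quinone and electrophile regulators lost its call at an estimated correlation of 0.019, near the preset of 0.01. This argues against correlation among the genes as the cause for that list. For the other lists, whether low power or correlation among the genes cost the call was not tested. Fry added bacillithiol (0.776), SigD (0.742), branched-chain (-0.405) and histidine and tryptophan genes (-1.19), and turned the direction of the HrcA list (median 1.01). OhrR lost its call with scaled arrays (4.605, adjusted p = 0.0677 in limma) and without replicate 1 (adjusted p = 0.0506) and replicate 3 (0.051), with medians from 4.549 to 4.662 over the left-out arrays; the cause was not tested. SigD gained a call without replicate 1, with medians from 0.624 to 0.86 over the left-out arrays, the cause not tested. The direction given by camera turned for glycolysis without replicate 2 (medians from 0.013 to 0.059 over the left-out arrays) and for HrcA without replicate 3 (medians 0.812 to 1.155, and 0.981 there), neither past the threshold and the cause not tested. Arginine synthesis (-6.944 to -3.34) gained its call without replicate 3, the array on which the decrease was smaller.

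Of the 114 named genes, all kept their call when arrays were centred, scaled or quantile normalized. The robust fit lost 5 (argC, artP, argG, argJ and argH), treat 2 (odhB and citG), and leaving out replicates 1, 2 and 3 lost 4, 7 and 1. Not run were the mean over probes and the filter on probe number or dim genes, since features carry no gene names and intensities were not used here, the filter on missing values, since none was missing, and the authors' table as an alternative, since it was the source. No separate paired analysis was run, because the ratio of each array already pairs a treated with an untreated RNA and there is 1 group of arrays. Signal over background was not used here, so its limit on weak genes is unknown.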

Other observations

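The lists and tests of this part were chosen after results had been seen, apart from the test of turned signs and that of operon order, whose operons were listed by name. The suf and tua genes stand both in an added list and among those operons, and none of their values had been seen when both were written. Phosphate transport and peptidoglycan precursor genes, which the fixed lists did not hold, also changed. Of 19 PhoP-controlled genes of phosphate starvation 8 were higher and 11 not called, with a median of 0.134 and a mean of 1.297, and of all 4105 genes 1500 were higher. The rise lay mainly in the phosphate transporter genes, pstS (4.95), pstC (4.73) and pstA (4.53) among them, while the regulator genes phoP and phoR had log2 ratios of 0.13 and 0.10 and were not called. All 6 genes for iron-sulphur cluster assembly were higher, with sufA at 2.81 (median 1.18). Of 11 genes of peptidoglycan precursor synthesis 10 were lower and 1 not called, lowest for murG (-3.47), mraY (-3.39) and murD (-3.36), and of 21 aminoacyl-tRNA synthetase genes 17 were lower, 1 higher and 3 not called (median -1.10); the higher gene was gltX (0.35). Limma's camera with Benjamini-Hochberg adjustment over the 6 added lists gave 0.0598, 0.00518, 2.44e-04 and 2.44e-04 in this order. The PhoP list thus did not pass camera. With an estimated correlation camera gave adjusted p = 0.673, 0.498, 0.407 and 0.298 (limma). Limma's fry called each of these lists, with Benjamini-Hochberg adjusted p = 0.0222, 0.00419, 0.00106 and 0.00106 in the same order. Fry does not set a list against the other genes, and 73.1% of all genes were called, so these values do not set the lists apart from the rest.

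The genes of arginine synthesis and uptake had a smaller decrease on the array of replicate 3: the 12 arg, car and art genes had medians of -6.50, -7.20 and -0.40 on the 3 arrays, a median loss of 94% of the decrease, with members on both sides of 0 there. Of these, 9 were called lower and 3 not called, against 1 (artP), 0 and 12 lower without replicates 1, 2 and 3; limma's camera gave a Benjamini-Hochberg adjusted p of 0.0261 over the 6 added lists (adjusted p = 0.673 with an estimated correlation) and fry 0.192, on genes picked for this pattern, so these values do not test it. A smaller decrease on the array of replicate 3 was not confined to arginine genes. The histidine and tryptophan list had medians of -1.6, -1.3 and -0.38 on the 3 arrays, although trpA, trpC and trpD kept their decrease. The branched-chain list had medians of -0.65, -0.47 and -0.1. A failure of the whole array of replicate 3 to show decreases is argued against by the pyr and pur genes. They lost a median of 0.7% of their decrease there. An error of the gene averaging stays open: 84 array features were at least 8 times higher there than on both others with the others at one eighth or less, but 0 were with the unstated direction of that table turned, and features carry no gene names. A candidate explanation is that the cultures differed in their arginine state, which cannot be told apart from other causes because the levels of the treated and untreated channels were not used here, and 12 genes stood apart by 4 or more on the log2 scale.

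The 9 zinc-responsive genes of the Zur regulon had medians of 3.52 and 2.66 on the arrays of replicates 1 and 3 and of -2.50 on that of replicate 2, although znuC and znuB were lower on every array. Called were znuC (-2.15 ± 1.40) and znuB (-1.88 ± 1.15), lower, and rpsNB (3.42 ± 1.32), higher, at -1.34, -1.22 and 4.15 without replicate 2 (camera in limma for the list, Benjamini-Hochberg adjusted p = 0.672, and 0.896 with an estimated correlation). A general failure of that array to show increases is argued against because the increased metal, PerR, Spx and CtsR genes lost a median of -12.1% there, that is, rose more. An error of averaging stays open: 40 unnamed features were at least 8 times lower on replicate 2 than on both others with replicate 2 at a ratio of 0.25 or less, and 12 were with the unstated direction turned. A rule written after the pattern was seen counted such numbers against an averaging error, and it was met in either direction. It was not applied, because features without gene names cannot be tied to the Zur genes. Cultures that differed in zinc state may account for the pattern, but with the channel levels not used here this cannot be told apart from other causes, and 7 Zur genes were at least 4 times lower on that array than on both others.

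Without the arginine and zinc genes, the lowest correlation between arrays was 0.948.

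The decrease of several operons became smaller along the gene order. The rank correlation of position with the change in the direction of the operon was -0.806 for pyr, -0.874 for pur, -0.957 for the ribosomal protein genes, -0.567 for atp and -1.0 for pdh. For trp (0.486) it went the other way. The run from hrcA (2.08) to mtaB (-1.86) had no single direction, and its value of 0.857 only follows from the sign of its mean of -0.662. These 7 had been picked with their values seen. One hypothesis is that the change reaches distal genes later, and it was put to 37 operons listed with no value seen but those of appA and mmgB, of which 9, none with these genes, had a mean change of at least 1 on the log2 scale: 5 of the 9 correlations lay below 0, with a mean of -0.067 (permutation p = 0.66 in 100000 shuffles of the gene order), so the test gave no evidence for it. The rule set beforehand would have counted a p of 0.05 or more over at least 8 operons against the hypothesis, and this rule was met; the reading was changed to undecided after the result was seen, because a missed threshold excludes nothing and 9 operons needed a mean of at least 0.293 in size to pass. A difference in RNA quality between the channels also stays open, since the 8 lower operons had a mean signed correlation of 0.013 (permutation p = 0.936) and only 1 operon was higher. No biological explanation was tested beyond the first.

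The count of 3001 called genes was set against the sets of signs obtained by turning 1 array. The real signs gave 3001, and the highest of the other 3 sets gave 0 in limma with Benjamini-Hochberg adjustment, with 0, 5 and 6 genes at an unadjusted p under 0.05. Only 1 of the 4 sets, the real one, reached the count, and 4 sets are too few for a share under 0.05. The arrays correlated at 0.924 or more, so turning 1 of them moves shared changes into the spread between arrays. Low counts in the turned sets were therefore bound to follow, and they give no chance level for the 3001 calls.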
